A study of Mus musculus with 4 samples.

How the data were processed

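Per the submitters' labels, libraries were made with the Chromium Single Cell 3' kit, version v3.1, and reads were processed by the authors with Cell Ranger 3.0 against mouse build mm10, as their processing notes state. The 1 kit of the labels is in doubt for some libraries: those of P60 and of P80 share 3 to 6 barcodes, where 201 to 438 would be shared by chance if all were drawn from a list of the size that fits P80 (613 shared within P80 against 647 by chance, and 34 within P60 against 136). The header of the deposited matrices gives Cell Ranger 7.0.0 instead. Other settings of the alignment and of the calling of cells are not given in the sources used here. Per the file headers and the values, which are whole numbers, each entry of the deposited matrices is a count of UMIs per gene and barcode, over 31054 features, among them the transgene egfp. The barcodes had been called as cells by the authors, and the smallest barcode total was 500 UMIs. Gene positions were not used here.

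The sham P60, PTS P60, sham P80 and PTS P80 libraries held 8538, 11760, 17392 and 27434 barcodes with 94116587, 118306595, 196413482 and 275828062 UMIs. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which left 7765, 11055, 16140 and 25777. Doublets were scored with Scrublet in each library. Where its own threshold marked under 0.5% of cells, as at P60, the highest scores were removed at the rate expected from loading, 0.8% per 1000 barcodes. This removed 530, 1040, 388 and 2229 cells (6.83%, 9.41%, 2.40% and 8.65%), against 13.9% and 21.9% expected at P80. Of the cells removed from sham P60, 207 of 530 held both Xist and Y-linked UMIs, and 432 of the 7235 kept cells did.

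Kept cells were log-normalised and clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, without batch correction. Clusters led by markers of another class than their own were clustered again once. A cluster took the name of the class among 18 whose fixed markers scored highest, with a score of at least 1 and at least 3 markers seen in at least 10% of its cells. Of 74 clusters, 14 took no name, and these held 3.99%, 3.37%, 8.08% and 6.99% of the kept cells of the 4 libraries. The 9 classes with at least 50 cells in every library were compared.

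UMIs were summed per class and library and scaled to CPM. Genes with at least 20 CPM in 1 or more libraries of the class entered the ratios, which had 1 CPM added to each side. Genes at least 2-fold apart in the same direction at both time points were counted beside the number that independent lists of the same sizes would share. The 28 gene lists were compared, where 5 or more members were measured, with 10000 random lists matched in 10 bins of mean expression, and a list was called apart below percentile 2.5 or above percentile 97.5 at both time points. The random lists describe these libraries and are not a test against the spread between animals. The surgery effect was tested with edgeR (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, surgery plus time point, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the summed counts. Its p-values measure the spread between samples, here the difference of the surgery ratio between the 2 time points with 1 residual degree of freedom, and animals cannot be separated from libraries. DESeq2 was fitted to the same counts. Cycling cells were counted after thinning to 2000 UMIs, and 75, 65, 358 and 315 neuroglia with fewer UMIs were left out.

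Markers, gene lists, comparisons and the rule for named genes were fixed before the data were examined. The rule ranked genes at least 2-fold apart in the same direction by the smaller of their absolute log2 ratios and took up to 10 each way in neuroglia, microglia-like and monocyte/macrophage-like cells and up to 4 each way in other classes. It left out genes with under 20 UMIs in the higher library of a time point, mitochondrial, ribosomal, haemoglobin and sex-linked genes, gene models without a name, and genes under 10% of their CPM in the class where they were highest. It added the 2 to 4 members with the largest mean absolute ratio of each list described, and the 3 with the largest ratio each way per time point in neuroglia and microglia-like cells. In B/plasma-like cells it took immunoglobulin variable segments, such as Igkv5-43 (6.41 at P60 and 9.15 at P80), which differ between clones.

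The chain of steps was tested on simulated data, drawn from a negative binomial around mean levels shared by sham and PTS at each time point, with 200 genes changed the same way at both. In neuroglia 80% of genes made 2.5-fold higher and 84% of those made 2.5-fold lower were called by the ratio limit, as were 100% of 4-fold changes, with 0 of 8854 unchanged genes. For edgeR 100% at both sizes and 9 unchanged genes were called. In microglia-like cells 86% and 84% of the 2.5-fold changes were called, 100% of the 4-fold changes and 0 of 6630 unchanged genes, with 6 unchanged genes for edgeR. None of 200 random lists lay apart. These simulations hold no spread between animals.

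A set of 34 other settings was fixed in advance: scaling (TMM, RLE size factors, the mean over cells), pseudocount, minimum CPM, fold limit, filters on cells and on low counts, doublet removal, clustering, DESeq2, the fit without time point, and thinning. A further 14 were chosen after the data had been seen: doublets at the expected rate in every library, neuroglia without clusters of 1 library, and P60 limited to cells with Y-linked and no Xist UMIs. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. Reads were not used here.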

Results

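The series holds single-cell RNA sequencing of brain tumours from mice with de novo high-grade glioma. The mice had sham surgery or surgery that gave them a stroke (labelled PTS), and tumours were taken at 2 time points, labelled P60 and P80. Tumours were dissected by their GFP signal, dissociated with papain, and passed through steps that remove red blood cells, debris and dead cells, so the libraries hold tumour cells together with the cells around them. There are 4 libraries, 1 for each surgery and time point, and no replicates. The number and sex of the animals behind a library are not given in the labels.

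Total counts of unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule) were 94116587 for sham P60, 118306595 for PTS P60, 196413482 for sham P80 and 275828062 for PTS P80. After filtering, these libraries held 7235, 10015, 15752 and 23548 cells. Median UMIs per kept cell were 7794, 7243, 9418.5 and 7151.5 in the same order. Values are UMIs scaled to a fixed library total (CPM, per 1e6 UMIs) summed over the cells of a class in a library, and a log2 ratio is PTS over sham within 1 time point with 1 CPM added to each side. Ranges in brackets and intervals are 95% intervals, which cover counting error only and carry no spread between animals. Those of shares and of their folds are exact binomial intervals. Those of log2 ratios are approximate, combined from the exact Poisson intervals of both counts. Classes are named after their markers and end in "-like". Astrocyte-like, oligodendrocyte progenitor (OPC)-like and glial progenitor-like clusters are pooled as neuroglia, since tumour cells and normal glia were not told apart.

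RNA from the sex chromosomes differed between the libraries. Xist, made from the inactive X chromosome in females, measured 550 CPM in sham P60, 0.771 CPM in PTS P60, 539 CPM in sham P80 and 379 CPM in PTS P80. The Y-linked gene Eif2s3y measured 29.0 CPM in sham P60 and 71.6 CPM in PTS P60, and had 0 UMIs in both P80 libraries. In sham P60, 3953 of 7235 kept cells (54.6%, interval 53.5 to 55.8) had Xist and no Y-linked UMIs, and 1848 cells (25.5%, interval 24.5 to 26.6) had Y-linked and no Xist UMIs. In PTS P60, 7435 of 10015 kept cells (74.2%, interval 73.4 to 75.1) had Y-linked and no Xist UMIs. The cell barcodes also differ by time point: barcodes that start with AAACCT occur 40 and 47 times in the sham and PTS libraries of P80 and 0 times in those of P60, so time point and barcode set go together, although the labels name 1 kit for all libraries.

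**Figure D1:**
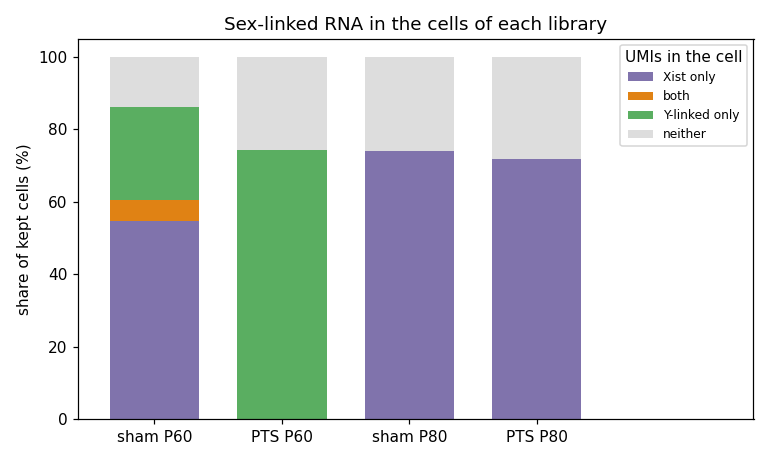
Share of kept cells (percent, vertical axis) with UMIs of Xist only, of both Xist and Y-linked genes, of Y-linked genes only or of neither, as stacked bars for the 4 libraries. Sham P60 holds 54.6% Xist and 25.5% Y-linked cells, PTS P60 74.2% Y-linked cells, and the P80 libraries 74.1% and 71.8% Xist cells and 0% Y-linked cells.

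The first comparison asked which cell classes took a different share of the tumour after stroke surgery. Monocyte/macrophage-like cells had a higher share with PTS at both time points, at 8.69% against 5.39% at P60 (1.61-fold, 1.43 to 1.82) and 12.8% against 10.3% at P80 (1.24-fold, 1.17 to 1.32). B/plasma-like cells, the antibody-producing lineage, were also higher at both, at 16.5% against 12.5% at P60 (1.32-fold, 1.22 to 1.44) and 5.41% against 0.584% at P80 (9.27-fold, 7.50 to 11.6). Oligodendrocyte-like cells, which make myelin, had lower shares at both, at 4.28% against 5.32% at P60 (0.805-fold, 0.700 to 0.926) and 5.48% against 7.51% at P80 (0.729-fold, 0.674 to 0.790). Choroid plexus-like cells were lower as well, at 0.429-fold (0.300 to 0.607) and 0.739-fold (0.555 to 0.984).

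Mural-like cells (0.607-fold and 0.765-fold) and ependymal-like cells (0.305-fold and 0.898-fold, the latter 0.657 to 1.23) had lower shares too, with fewer than 50 cells in a library. Other classes among the 9 compared did not keep 1 direction. Neuroglia were 9.38% with PTS against 13.2% with sham at P60 (0.710-fold, 0.648 to 0.778) and 28.5% against 23.5% at P80 (1.21-fold, 1.16 to 1.26). Microglia-like cells, the resident macrophages of the brain, were 26.1% against 22.5% at P60 (1.16-fold, 1.09 to 1.23) and 19.5% against 26.8% at P80 (0.726-fold, 0.696 to 0.757). T/NK-like lymphocytes were 0.951-fold (0.898 to 1.01) at P60 and 1.18-fold (1.12 to 1.25) at P80. Endothelial-like cells, which line blood vessels, were 1.01-fold (0.799 to 1.29) at P60 and 0.479-fold (0.437 to 0.525) at P80.

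The shares were not tested, and with 1 library per group their spread between animals is not known. Within sham P60, B/plasma-like cells were 0.379% of the Y-linked cells (7 of 1848) and 19.1% of the Xist cells (754 of 3953), and with P60 limited to Y-linked cells in both libraries the P60 fold was 43.9 for B/plasma-like, 2.29 for monocyte/macrophage-like, 1.54 for T/NK-like, 0.595 for endothelial-like, 0.957 for microglia-like, 0.557 for oligodendrocyte-like and 0.303 for neuroglia cells. That of choroid plexus-like cells was 0.771 (0.368 to 1.76), from 10 sham cells, and with doublets removed at the expected rate their P80 fold was 0.985 (0.702 to 1.39), so neither is apart from 1. Without doublet removal the share of neuroglia at P80 turned to 0.833-fold and that of microglia-like cells at P60 to 0.853-fold. The latter also turned with finer clusters, at 0.959-fold, and T/NK-like cells at P80 turned to 0.950-fold with cells of at least 2000 UMIs. Without doublet removal clusters were also formed and named anew, so those turns are not of doublets alone. An astrocyte-like cluster with a median of 1656.5 UMIs then held 1627 sham P80 cells. A Postn-led cluster with 717 PTS P80 cells was then fibroblast-like. A cluster led by Ccl8 and Apoc1, with 296 sham and 1025 PTS cells of P60, took no name.

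**Figure D2:**
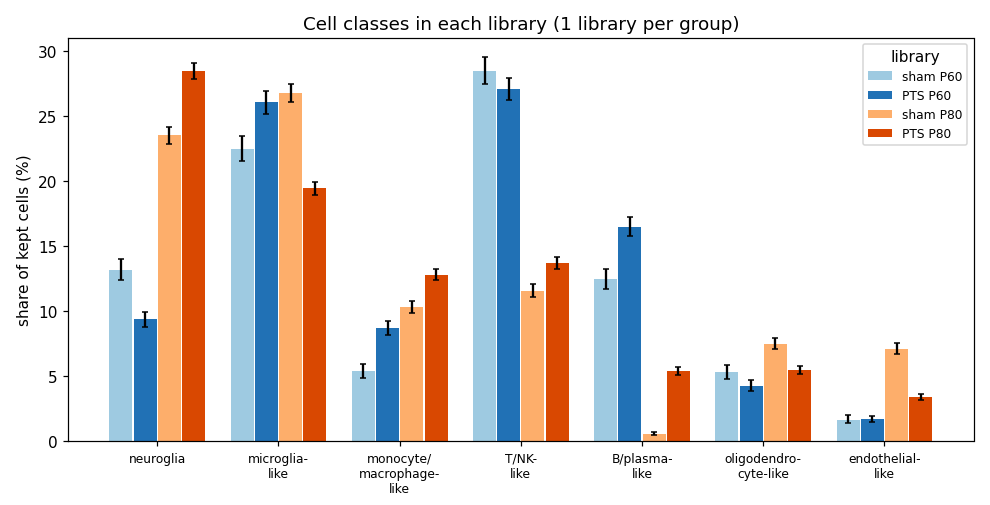
Share of kept cells (percent, vertical axis) in 7 cell classes for the 4 libraries, as bars with exact 95% binomial intervals that cover counting error only. Monocyte/macrophage-like and B/plasma-like cells are higher with PTS at both time points, and neuroglia and microglia-like cells differ in direction between them.

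The second comparison asked how the RNA of each class differed between stroke and sham surgery, and which differences ran the same way at P60 and P80. In microglia-like cells Chil1 (ENSMUSG00000064246), a chitinase-like secreted protein, was higher with PTS by a log2 ratio of 4.02 (3.80 to 4.25) at P60 and 5.91 (5.71 to 6.10) at P80. Fn1, which encodes the matrix protein fibronectin, was higher by 2.61 (2.48 to 2.74) and 3.18 (3.11 to 3.24). Spp1, which encodes the secreted protein osteopontin, went from 692 CPM in sham to 2269 CPM in PTS at P60 and from 524 to 6148 CPM at P80. Saa3, an acute-phase protein, was higher by 2.03 and 1.52, although without doublet removal it was lower at P80, at −0.40. Npl was higher by 1.90 and 1.47, Cdo1 by 1.61 and 1.60, and Wfdc17 by 1.14 and 1.88. Cd38 was 2.46-fold and 2.98-fold higher, and the apolipoprotein gene Apoc4 2.46-fold and 7.06-fold. Siglech (ENSMUSG00000051504), a lectin of resting microglia, was lower, at −1.08 (−1.18 to −0.99) and −2.28 (−2.32 to −2.24). The calcium channel subunit gene Cacnb4 measured −1.33 and −2.97, the potassium channel gene Kcnk12 −1.15 and −1.80, and Slc24a3 −1.04 and −1.10. Pilra measured 95.2 CPM in sham and 28.5 CPM in PTS at P60 and 83.1 and 41.0 CPM at P80, and Chn2 66.3 and 32.4 CPM at P60 and 129.9 and 45.3 CPM at P80.

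The fixed list of homeostatic microglia genes, those of microglia at rest, had median log2 ratios of −0.37 at P60 and −0.64 at P80, and 13 of its 13 measured members were lower with PTS at both time points. P2ry12, a nucleotide receptor, measured −0.54 and −1.36, Selplg −0.79 and −1.27, and Gpr34 −0.95 and −0.64. The disease-associated microglia list had medians of 0.11 and 0.54, with 9 of 17 measured members higher at both. Among them Gpnmb measured 0.82 and 3.36 and the lipid carrier gene Fabp5 0.99 and 2.22, while Igf1 measured −0.01 and 3.73. The alternative activation list had medians of 0.21 and 0.41, with the arginine-degrading enzyme gene Arg1 at 2.51 and 3.81 and Msr1 at 0.38 and 2.95. Glycolysis (0.16 and 0.45), oxidative phosphorylation (0.12 and 0.42), hypoxia (0.12 and 0.47) and G2/M phase genes (0.06 and 0.76) also had higher medians in microglia-like cells. Genes of the immediate-early and dissociation stress response had medians of −0.51 and −0.30. All 8 of these lists lay outside the central 95% of 10000 random lists of matched expression at both time points. Some of the P60 values turned: without doublet removal hypoxia measured −0.12, alternative activation −0.17 and glycolysis −0.11, and G2/M measured −0.14 with a mean over cells and −0.08 with Y-linked cells at P60. With those cells the P60 medians of other lists were 0.74 for disease-associated microglia, 0.41 for glycolysis, 0.23 for oxidative phosphorylation and 0.04 for hypoxia, the last no longer outside the central 95%.

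In microglia-like cells 12 genes were at least 2-fold higher and 11 at least 2-fold lower with PTS at both time points, of 6991 compared. Independent lists of these sizes would share 0.461 and 1.04 genes, and 3 genes passed this limit in opposite directions. Pearson r of the ratios at P60 and P80 was 0.383 and Spearman rho 0.452, across genes, which are not independent replicates. The median of all genes was −0.11 at P60 and −0.10 at P80 with CPM, against 0.05 and 0.03 with TMM scaling, under which the homeostatic list measured −0.21 and −0.52 and the counts were 20 higher and 4 lower. Without doublet removal r was 0.124, below the 0.275 of oligodendrocyte-like and 0.231 of B/plasma-like cells, and the counts were 7 and 3.

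Surgery was tested with edgeR's quasi-likelihood test with time point as a covariate, which leaves 1 residual degree of freedom and takes the difference between the time points as the spread. In microglia-like cells 0 of 15874 genes passed an adjusted p of 0.05 (unadjusted p under 0.05: 1006 higher, 907 lower), and DESeq2 called 96 higher and 84 lower. Adjusted over the list alone, 3 of 13 homeostatic genes fell (Gpr34, Selplg and Siglech), and 5 of 17 disease-associated (Apoe, Cd63, Fabp5, Gpnmb and Spp1), 4 of 15 alternative activation and 7 of 28 G2/M genes rose, against 0 of each over all genes. The other 4 lists gave 0 both ways. With P60 limited to Y-linked cells, edgeR called 248 genes higher and 164 lower. At P60, 90.8% of sham and 91.6% of PTS microglia-like cells lay in 1 cluster, whereas at P80 the cluster with the most cells held 43.7% of them in sham and another held 41.8% in PTS. The clusters of P60 differed without doublet removal. There a microglia-like cluster held 1187 sham and 1445 PTS cells of P60. An unnamed cluster led by Ccl8, Apoc1, H2-M2 and Chil1 held 296 and 1025.

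**Figure D3:**
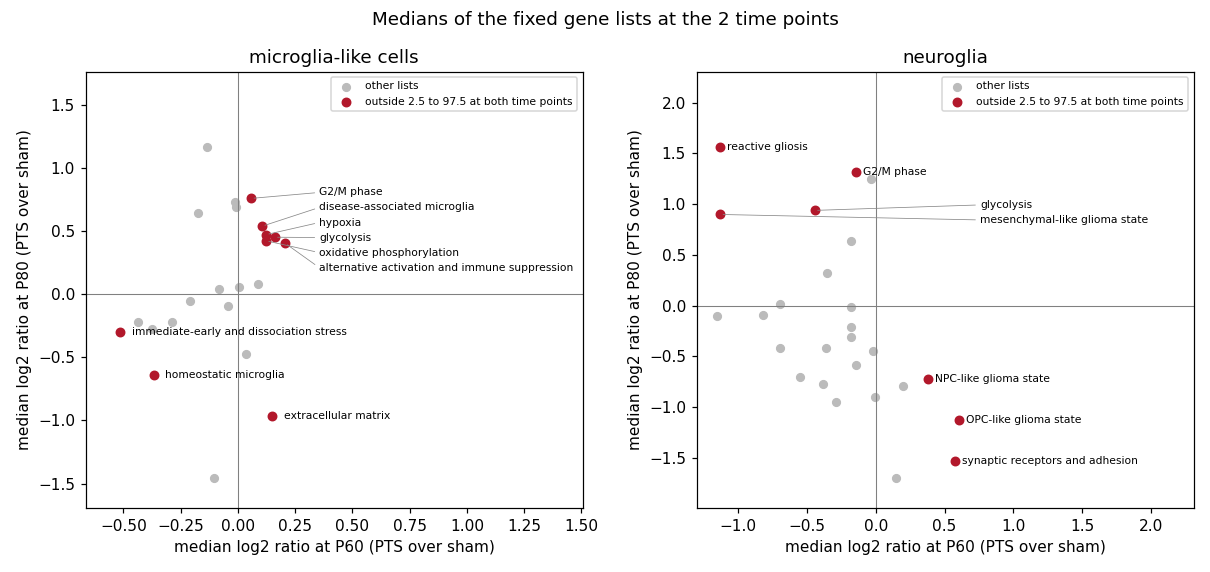
Median log2 ratio (PTS over sham) of each fixed gene list at P60 (horizontal axis) and P80 (vertical axis) in microglia-like cells and in neuroglia, with 1 point per list and, in red and named, those outside the central 95% of random lists at both time points. In microglia-like cells the homeostatic list lies at −0.37 and −0.64 (−0.21 and −0.52 with TMM scaling), and in neuroglia the reactive gliosis list lies at −1.13 and 1.56.

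The largest ratios at 1 time point in microglia-like cells included that of Pde4d, a cyclic AMP phosphodiesterase gene, which measured −3.30 at P60 and 1.23 at P80. Inside sham P60 Pde4d measured 987 CPM in Y-linked and 41.2 CPM in Xist cells. Its P60 fall thus rests largely on the Y-linked sham cells. The heat shock genes Hspa1b and Hspa1a measured −1.98 and −1.80 at P60 with 0.15 and 0.29 at P80, and Dennd5b measured 3.68 at P60 and −0.33 at P80. At P80, Klrk1 measured 3.83, against −0.18 at P60, and St8sia6 and Ccr6 measured −3.05 and −2.52, against −0.77 and −0.17 at P60.

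In monocyte/macrophage-like cells Chil1 was again the gene with the highest ratios in the same direction, at 2.69 (2.49 to 2.89) at P60 and 6.68 (6.42 to 6.94) at P80. With P60 limited to Y-linked cells its P60 ratio was 0.26 and that of Fn1 0.51, against 1.20 for Fn1 in all cells. Npl went from 11.3 to 68.8 CPM at P60 and from 8.69 to 106 CPM at P80. The secreted macrophage protein gene Cd5l measured 1.28 and 2.25, Chst1 1.13 and 2.53, and the phospholipid transfer gene Pltp 1.04 and 1.07. Inhba, which encodes an activin subunit, was lower, at −2.05 (−2.59 to −1.52) and −3.08 (−3.33 to −2.83), and the complement gene C2 measured −1.30 and −1.23. S100a9, an alarmin of neutrophils and monocytes, had 7.27 CPM in sham and 0 UMIs in PTS at P60, and 42.1 against 2.05 CPM at P80. Inside sham P60, Inhba measured 92.0 CPM in 70 Y-linked cells and 4.19 CPM in 265 Xist cells. S100a9 measured 48.3 and 0.299 CPM there, so the P60 falls of these genes rest largely on the Y-linked sham cells. C2 measured 46.8 and 47.8 CPM there.

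In monocyte/macrophage-like cells 5 lists had lower medians than random lists at both time points. Inflammatory cytokines measured −0.56 and −0.77, with 11 of 15 members lower at both, among them Tnf at −0.79 and −1.12, Cxcl2 at −0.72 and −1.17 and Il1a at −0.56 and −1.39. Hypoxia genes measured −0.30 and −0.79, with 15 of 16 lower, among them the glucose transporter gene Slc2a1 at −0.61 and −1.16. Interferon response measured −0.33 and −0.24 (16 of 20 lower) and MHC class I −0.24 and −0.81 (9 of 11 lower). Complement measured −0.21 and −0.52 (6 of 11 lower), with Serping1 at −2.19 and −0.90, although with Y-linked cells at P60 its median there was 0.21. With those cells hypoxia measured −0.01 and MHC class I −0.23 at P60, and neither lay outside the central 95% of random lists there, while interferon response measured −0.94.

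At least 2-fold differences in the same direction were found for 8 higher and 7 lower genes of 6832 in monocyte/macrophage-like cells, where independent lists would share 0.832 and 2.76, and 13 genes passed in opposite directions. Pearson r was 0.154 and Spearman rho 0.252 across genes. The edgeR test called 0 of 13643 genes (unadjusted p under 0.05: 344 higher, 643 lower) and DESeq2 5 higher and 2 lower, and with Y-linked cells at P60 edgeR called 54 higher and 37 lower. Adjusted over the list alone, 4 of 17 inflammatory cytokine genes (Cxcl2, Il6, Nlrp3 and Tnf) and 5 of 12 complement genes fell, against 0 over all genes, and hypoxia, interferon response and MHC class I gave 0. At P80, 98.3% of the sham cells lay in a cluster that held 13.1% of the PTS cells.

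**Figure D4:**
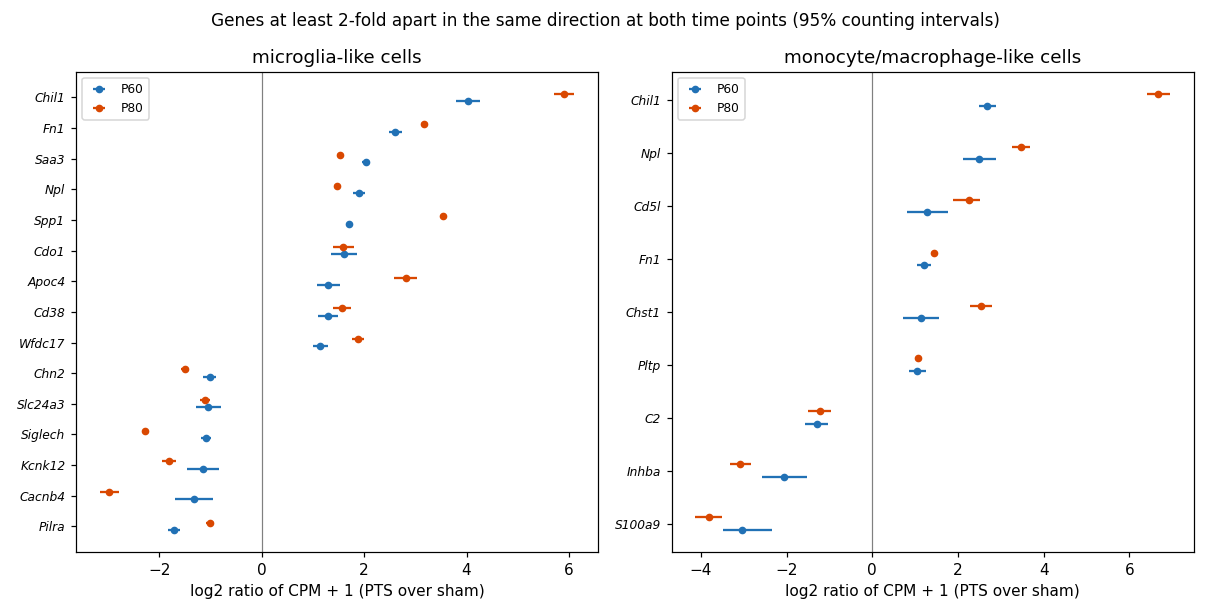
Log2 ratio of CPM + 1 (PTS over sham, horizontal axis) at P60 and P80 of the genes at least 2-fold apart in the same direction in microglia-like and in monocyte/macrophage-like cells, as points with approximate 95% intervals that cover counting error only. Chil1 has the highest ratios in both classes, at 4.02 and 5.91 in microglia-like and 2.69 and 6.68 in monocyte/macrophage-like cells.

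In neuroglia 7 of 27 gene lists lay on opposite sides of random lists at P60 and P80. Reactive gliosis genes, raised in astrocytes after injury, had a median of −1.13 at P60 and 1.56 at P80. The intermediate filament gene Gfap measured −1.08 and 1.82, S100a10 −2.18 and 2.20, and Lcn2 −6.58 and 1.83. The mesenchymal-like glioma state list measured −1.13 and 0.90, with Anxa1 at −2.64 and 2.09 and Lgals1 at −1.77 and 2.21. It shares Vim, Cd44, S100a6 and Emp1 with the reactive gliosis list, so these are not separate results. Glycolysis measured −0.44 and 0.94, with the lactate dehydrogenase gene Ldha at −0.44 and 2.08. The OPC-like glioma state list measured 0.61 and −1.13, with the matrix gene Tnr at 1.20 and −3.47 and Neu4 at 1.41 and −2.56. Synaptic receptors and adhesion genes measured 0.58 and −1.53. The NPC-like glioma state list, named after neural progenitors, measured 0.38 and −0.72, with the transcription factor gene Dlx5 at 1.83 and −3.98 and Dcx at 1.58 and −2.16. Without the 2 clusters found nearly only in 1 library its P80 median was 0.01.

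Some genes of neuroglia kept their direction. Egfr (ENSMUSG00000020122), a growth factor receptor often altered in glioma, was higher by 1.86 (1.81 to 1.91) at P60 and was 2.83-fold higher at P80, going from 291 to 1062 CPM at P60 and from 63.8 to 183 CPM at P80. Egfros, an antisense RNA that overlaps Egfr, measured 1.95 and 1.04, and reads of overlapping genes are not told apart here. Svep1 measured 1.60 and 1.37, the axon guidance gene Draxin 1.31 and 1.32, Tbrg4 1.33 and 1.21, the homeobox gene Dbx2 1.12 and 1.61, the Wnt receptor gene Fzd9 1.10 and 1.80, Ddx56 1.04 and 1.49, and the lipogenic gene Thrsp 1.06 and 3.44. Cma1, a mast cell protease gene, measured 4.95 at P60 and was 2.00-fold higher at P80. Pdlim3 was lower, at −2.36 (−2.62 to −2.11) and −2.61 (−2.70 to −2.53), and the neuropeptide gene Npy measured −1.82 and −1.93. Also lower were Serpind1 (−1.62 and −3.37), Dlgap2 (−1.34 and −2.98), Fxyd7 (−1.62 and −1.30), Tns2 (−1.26 and −1.42), Fam129b (−1.23 and −1.41), Fam89a (−1.20 and −2.34) and Pde4d (−1.26 and −1.76). Abca8a measured −2.13 and −1.74, although 0.38 at P60 without doublet removal. Several of these lower genes also differed inside sham P60. Pdlim3 measured 89.5 CPM in Y-linked and 10.8 CPM in Xist cells there, Npy 70.9 and 7.98, and Fxyd7 73.1 and 12.1. Fam89a measured 102 and 35.4 CPM, Abca8a 16.7 and 1.91, and Pde4d 1456 and 264, while Dlgap2 measured 16.9 and 93.5. Their P60 ratios thus depend on which sham cells are used, and ratios against Xist cells alone were not computed.

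The genes of neuroglia with the highest ratios at 1 time point were, at P60, Tfap2c with 0 UMIs in sham and 635 in PTS, and Tenm2 at 3.98 with −2.08 at P80, and at P80 Fbp2 at 6.40, Fndc3c1 at 4.79 and the homeobox gene Hoxa7 at 4.77. The lowest were, at P60, Lcn2, Pcp4l1 at −3.72 and Col6a5 at −3.65, and at P80 Etl4 at −5.84, Matn1 at −4.69 and Tmem178 at −4.60.

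The ratios of neuroglia at P60 and P80 had a Pearson r of −0.308 and a Spearman rho of −0.312 across 9538 genes. The genes at least 2-fold apart in the same direction, 11 higher and 25 lower, were fewer than independent lists would share (26.2 and 37.4), and 241 genes passed in opposite directions. Without the 2 clusters found nearly only in 1 library this shortfall ended (9 and 19 against 8.75 and 18.7), and with no minimum CPM it turned (33 and 63 against 29.5 and 51.0). None of the lists lay on the same side of random lists at both time points. The edgeR test called 0 of 18031 genes (unadjusted p under 0.05: 129 higher, 177 lower) and DESeq2 called 6 higher and 9 lower. Adjusted over the list alone, reactive gliosis, mesenchymal-like, OPC-like, NPC-like, synaptic, glycolysis and G2/M genes gave 0. Clusters of neuroglia differed by library: 2174 of the 2178 cells of 1 astrocyte-like cluster came from PTS P80 and 525 of the 546 cells of 1 OPC-like cluster from sham P80. At P60 a cluster whose leading genes include Egfr held 58.4% of PTS and 23.2% of sham neuroglia, and a cluster led by Postn held 37.3% of sham neuroglia and 41 of 939 PTS cells. The class of the latter is not firm. Without doublet removal a cluster with the same leading genes took the fibroblast-like name, at a score of 1.60 against 1.56 for glial progenitor. The transgene egfp measured 298 CPM in sham and 1469 CPM in PTS neuroglia at P60, and 5275 and 6318 CPM at P80, against 2.73, 6.37, 226 and 293 CPM in microglia-like cells of the 4 libraries. It was not particular to neuroglia. Oligodendrocyte-like cells had 630 CPM in sham and 795 CPM in PTS at P60, and 2069 and 2458 CPM at P80.

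The share of cycling cells among neuroglia was compared after each cell was thinned to 2000 UMIs, counting cells with UMIs of at least 3 G2/M genes. At P80 it was 33.3% with PTS (2129 of 6389) against 10.5% with sham (350 of 3349), a fold of 3.19 (2.85 to 3.58). At P60 it was 19.2% with PTS (168 of 874) against 17.2% with sham (151 of 880), a fold of 1.12 (0.894 to 1.40), so no difference was detectable at this depth. The median of the G2/M phase list in neuroglia was −0.14 at P60 and 1.31 at P80, with Cdc20 at −0.48 and 2.16. In oligodendrocyte-like cells the share was 0.549% and 0% for sham and PTS at P60, and 3.01% and 4.75% at P80. They were set as a background for free RNA, but whether they include tumour cells was not tested. Their egfp measured 2069 CPM in sham and 2458 CPM in PTS at P80. Without the 2 clusters found nearly only in 1 library the P80 fold was 1.91, and without thinning the folds were 0.884 at P60 and 2.12 at P80.

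In oligodendrocyte-like cells some genes passed the edgeR test. Sgk1 (ENSMUSG00000019970), a kinase induced by glucocorticoids, rose by 1.83 in the edgeR fit (adjusted p = 0.00141), from 125 to 416 CPM at P60 and from 145 to 563 CPM at P80. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.76 (adjusted p = 0.00141), Tspan4 by 2.04 (adjusted p = 0.000781) and Steap3, a metalloreductase gene, by 2.10 (adjusted p = 0.00458). Fbn2, which encodes a fibrillin, fell by 2.57 (adjusted p = 0.000300), Pdzrn3 fell by 2.16 (adjusted p = 0.00492) and Dpp6 fell by 1.65 (adjusted p = 0.00440). Cntn3 measured −1.32 at P60 and −6.43 at P80 and did not pass.

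The mesenchymal-like glioma state list had medians of 0.93 and 0.98 in oligodendrocyte-like cells, with 16 of 16 measured members higher at both time points, among them Lgals3 at 1.38 and 3.61, S100a11 at 1.37 and 1.23 and Tnfrsf1a at 1.36 and 1.16. Of its genes 8 rose over all genes, and 15 of 19 adjusted over the list alone. Reactive gliosis measured 0.63 and 1.04 (Serpina3n 0.73 and 2.22), with 0 rising over all genes and 6 of 11 adjusted over the list alone. Disease-associated microglia genes measured 0.30 and 0.39 (2 rose, and 2 of 17 over the list alone), glycolysis 0.23 and 0.28 (1, and 2 of 13) and hypoxia 0.21 and 0.24 (1, and 1 of 18). Differences of at least 2-fold in the same direction were found for 47 higher and 7 lower genes of 7941 (3.33 and 0.698 by independent lists, with 14 in opposite directions). With each library clustered alone they were 52 and 5, with 90 in opposite directions. Pearson r then turned from 0.202 to −0.0678. In all, 101 of 13317 genes rose and 40 fell, and DESeq2 called 41 and 24. The genes that rose included immunoglobulin and T cell genes such as Cd3g and Ctla4, and immunoglobulin RNA was 0.272% of UMIs in sham and 0.537% in PTS at P60, and 0.0549% and 1.28% at P80. The calls ended in a fit without the time point covariate and with each library clustered alone (0 both ways in each), and 4 rose and 0 fell without doublet removal. With Y-linked cells at P60, 42 rose and 6 fell.

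In endothelial-like cells Slpi (ENSMUSG00000017002), a secreted protease inhibitor, rose by 6.48 in the edgeR fit (adjusted p = 1.38e-07). Its log2 ratio was 5.16 (4.47 to 5.94) at P60 and 6.84 (6.44 to 7.24) at P80, but at P60 it was −0.45 with each library clustered alone and −2.07 without doublet removal. The sulfotransferase gene Sult1a1 rose by 3.04 (adjusted p = 2.84e-06) and the transcription factor gene Zbtb16 by 2.67 (adjusted p = 2.51e-05). Ptgs2, which encodes the prostaglandin-making enzyme COX-2, fell by 1.76 (adjusted p = 5.35e-05). The interferon-induced gene Cxcl10 fell by 2.19 (adjusted p = 8.07e-05) and Ifit2 fell by 1.38 (adjusted p = 0.000367), and Cxcl10 at P60 was 0.25 without doublet removal. Hspa1a, a heat shock gene, fell by 1.39 (adjusted p = 0.000413).

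The interferon response list had medians of −0.38 and −0.71 in endothelial-like cells, with 18 of 19 members lower at both. Of its genes 4 fell over all genes, and 14 of 20 adjusted over the list alone. Immediate-early and dissociation stress genes had medians of 0.38 and 0.21, with Fos at 0.59 and 1.24 and Egr1 at 0.90 and 0.36. Of these 2 rose and 2 fell over all genes, and 9 rose and 2 fell adjusted over the list alone. Differences of at least 2-fold in the same direction were found for 27 higher and 41 lower genes of 8243 (4.09 and 9.08 by independent lists, with 48 in opposite directions). In all, 53 of 11615 genes rose and 89 fell, and DESeq2 called 5 and 8. The genes that rose included immunoglobulin genes such as Ighv1-53 and mast cell proteases, and those that fell included the glial genes Gpr17, Tnr and Bcan. Immunoglobulin RNA was 0.509% and 1.38% of UMIs in sham and PTS endothelial-like cells at P60, and 0.00352% and 2.05% at P80. Haemoglobin RNA was 1.43% in sham and 0.195% in PTS at P60, where 82.6% and 88.8% of the cells lay in a cluster led by Hbb-bs and Hba-a1. Without doublet removal 33 rose and 16 fell, and the class had 121 and 170 cells at P60. The fit without the time point covariate gave 0 both ways, as in all 9 classes.

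In dendritic-like cells, which present antigen, Il12b, encoding a subunit of interleukin-12, rose by 1.22 (adjusted p = 0.00397), and Dcstamp, a fusion receptor gene, fell by 1.80 (adjusted p = 0.000179). Ckb also rose by 1.08 (adjusted p = 0.0248), and Ifi27l2a fell by 1.20 (adjusted p = 0.00593). Both were chosen after their values were seen and complete the 2 genes that rose and 2 that fell among 9016. DESeq2 called 1 higher and 2 lower. The edgeR calls ended without the time point covariate and with each library clustered alone (0 both ways in each), and 1 rose and 0 fell without doublet removal. The interferon response list measured −0.36 and −0.37 (1 fell over all genes and 1 adjusted over the list alone), although 0.07 at P60 without doublet removal. The T cell activation and exhaustion list measured −0.55 and −0.49, with 0 falling over all genes and 2 of 11 adjusted over the list alone. Itgb8 measured 1.66 and 1.14, Hist1h2ae 1.27 and 2.20, Klri1 1.17 and 2.48, and Cacnb2 −1.19 and −1.45. With each library clustered alone Hist1h2ae was −0.93 and Klri1 −0.46 at P60.

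In T/NK-like cells Il4, the type 2 cytokine gene, measured 1.41 (0.87 to 1.80) at P60 and 2.51 (2.19 to 2.83) at P80, Tff1 2.35 and 2.44, the mast cell protease gene Mcpt2 1.40 and 5.89, and Grik4 1.38 and 1.76. Il4 was near the floor at P60, with 0.412 CPM in Y-linked and 0 CPM in Xist cells of sham, so its ratio there depends on the 1 CPM added. The class includes a cluster of 50 cells led by Mcpt1 and Mcpt2, of which 39 came from PTS P80 and 11 from sham P80. Which cells of the class held Il4 was not examined. Gzmc, which encodes a granzyme of killer lymphocytes, measured −3.18 and −3.11, and −0.39 at P60 with Y-linked cells there. The T cell activation and exhaustion list measured −0.17 and −0.19, with Gzma at −0.92 and −1.34, and 0.09 at P60 with Y-linked cells there. At least 2-fold differences in the same direction were found for 16 higher genes and 1 lower gene of 7649 (0.782 and 0.644 by independent lists), and 13 passed in opposite directions. Pearson r was −0.0143 and Spearman rho −0.116 across genes, and r turned to 0.295 with Y-linked cells at P60, 0.123 with each library clustered alone, 0.103 without doublet removal and 0.0892 with a mean over cells. The edgeR test called 0 of 14463 genes (unadjusted p under 0.05: 290 higher, 200 lower), DESeq2 25 higher and 5 lower, and 0 of the 20 list genes passed adjusted over the list alone. With P60 limited to Y-linked cells edgeR called 112 higher and 22 lower, and 64 genes were higher and 8 lower at both time points.

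In choroid plexus-like cells, which make cerebrospinal fluid, MHC class II genes had medians of −0.51 and −0.78, with H2-Ab1 at −0.70 and −1.07, and complement genes −0.74 and −0.72, with C3 at −2.67 and −1.64. Ifitm1 measured −2.57 and −3.94, Gbp5 −1.57 and −1.82, Ccbe1 −1.64 and −1.81, and Cks1b 1.67 and 1.41, the latter −0.13 without doublet removal. The rule for named genes also took Igkv12-44 (3.85 and 12.13) and Iglc1 (1.34 and 5.63) here, and immunoglobulin RNA was 8.06% of UMIs in sham and 5.75% in PTS at P60, and 0.00433% and 5.01% at P80. Of the complement genes 3 of 10 passed adjusted over the list alone and none of the MHC class II genes did, and edgeR called 0 of 9324 genes over all genes (unadjusted p under 0.05: 116 higher, 198 lower; DESeq2 1 and 2). In B/plasma-like cells MHC class II genes measured −0.19 at P60 and −1.72 at P80, where the median of all genes was −1.07 and immunoglobulin RNA made up 47.7% of UMIs with PTS and 5.06% with sham. At P80, 91.3% of the sham cells lay in a cluster led by Ms4a1 and Cd79a that held 18.7% of the PTS cells, and 62.2% of the PTS cells lay in a cluster led by immunoglobulin genes. None of these genes passed adjusted over the list alone, and edgeR called 0 of 13735 genes (unadjusted p under 0.05: 121 higher, 121 lower; DESeq2 36 and 7). With each library clustered alone edgeR called 39 higher and 4 lower, and with no filter on low counts 91 and 29.

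The last comparison set P80 beside P60 within each surgery, where the barcode set and the sex-linked RNA differ too. In microglia-like cells G2/M genes had a median log2 ratio (P80 over P60) of 2.26 in sham and 2.99 in PTS, and homeostatic genes 1.34 and 0.90. In neuroglia OPC-like glioma state genes measured 2.22 in sham and −0.31 in PTS, and glycolysis genes −0.05 and 1.27. In T/NK-like cells G2/M genes measured 1.26 and 0.30. OPC-like genes measured 3.71 and 2.30 in microglia-like and 3.39 and 2.12 in T/NK-like cells, which are both outside the oligodendrocyte lineage. The share of microglia-like cells with egfp UMIs was 2.40% in sham P60 and 89.6% in sham P80, and 5.10% and 77.7% with PTS. For T/NK-like cells it was 2.23% and 89.5% in sham, and 4.09% and 77.6% with PTS. The cause was not tested.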

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

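The test without neuroglia clusters of 1 library and that of B/plasma-like shares inside sham P60 were chosen only after the result was seen, as was the limit of P60 to Y-linked cells. Apart from the patterns of microglia-like and B/plasma-like cells weighed below, which kept 1 direction, the values differ in direction between P60 and P80 under the same surgery contrast, and the difference itself was not tested.

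In neuroglia the fold of the share (PTS over sham) was 0.710 at P60 and 1.21 at P80. The medians of the gene lists of neuroglia were −0.14 and 1.31 for G2/M phase, −1.13 and 1.56 for reactive gliosis, −1.13 and 0.90 for the mesenchymal-like state, 0.61 and −1.13 for the OPC-like state, 0.38 and −0.72 for the NPC-like state, 0.58 and −1.53 for synaptic receptors and adhesion, and −0.44 and 0.94 for glycolysis. Clusters found nearly only in 1 library do not account for the negative correlation across genes as a whole, since without them Pearson r was still −0.281, but without them the NPC-like list measured 0.01 at P80 and the genes in the same direction, 9 higher and 19 lower, were as many as independent lists would share (8.75 and 18.7). Other shifts in the mix of neuroglia stayed in that setting. Glial progenitor-like cells were 3.07% of sham and 5.47% of PTS kept cells at P60, and 3.31% and 1.49% at P80. OPC-like cells were lower with PTS at both (5.79% and 1.80%, 14.2% and 11.3%). Astrocyte-like cells were 4.34% and 2.11%, then 6.06% and 15.7%, the last mostly from 1 removed cluster. A change of mix and a change within cells are not told apart here. Differences between tumours of single animals may account for them: inside sham P60, 810 genes of neuroglia were at least 2-fold apart between Y-linked and Xist cells, against 413 between PTS and sham at P60. These counts are not alike, since the first rests on 545 and 178 cells and the second on a sham library that holds both kinds. With Y-linked cells in both P60 libraries, 440 genes were at least 2-fold higher and 240 lower with PTS, of 9557. The excess of 810 over 413 is thus no measure of how large animal differences are. Sex and animal are not separable inside sham P60, and an effect of stroke that differs with tumour age stays open and untested.

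Microglia-like cells had lower homeostatic genes and higher Chil1, Fn1 and Spp1 with PTS at both time points. Cells or RNA of the monocyte/macrophage-like class among them are argued against. They would need to make up 80.5% of the cells at P60 and 116% at P80. Other macrophage genes reached a median of 0.0356 of the rise needed at P60, with 3 of 56 such genes above 0.5 of it at P80. Other macrophages named microglia-like stay open, since the levels used were those of that class. Without doublet removal an unnamed cluster led by Ccl8, Apoc1, H2-M2 and Chil1 had 296 sham and 1025 PTS cells of P60. It scored highest for microglia, with 1 marker detected. The mix of sexes in sham P60 is argued against too, since with Y-linked cells alone the homeostatic median at P60 was −0.78, against −0.37 with all cells. Differences between animals of 1 group may be large enough, because the homeostatic list differed inside sham P60 by a median absolute log2 ratio of 0.614, but this does not cover Chil1 in microglia-like cells, which measured 11.7 and 5.13 CPM there against 141 CPM in PTS P60, although it measured 235 and 8.07 CPM in monocyte/macrophage-like cells of sham P60. An effect of stroke on microglia stays open beside it as a hypothesis, and 1 library per group does not separate them.

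B/plasma-like cells had a higher share with PTS at both time points, 9.27-fold at P80. Free immunoglobulin RNA as the only source is argued against, because 97.9% of these cells in PTS P80 had UMIs of at least 2 of 7 markers that are not immunoglobulin genes, against 1.18% of T/NK-like cells there. These 7 are among the markers that named the clusters, so the naming itself favoured a high share. Differences between animals of 1 group may account for the pattern: inside sham P60 the share differed 50.4-fold (24.3 to 126) between Xist and Y-linked cells. An effect of stroke surgery stays open and untested against them.

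The share of microglia-like cells was 1.16-fold at P60 and 0.726-fold at P80. The share of neuroblast-like cells was 0.185-fold at P60 (156 sham and 40 PTS cells) and 2.24-fold at P80 (20 and 67 cells), where it turned to 0.197-fold with doublets removed at the expected rate. The share of neutrophil-like cells was 0.0516-fold (0.00122 to 0.339) at P60 and 27.4-fold (4.65 to 1109) at P80, from 14, 1, 1 and 41 cells in sham P60, PTS P60, sham P80 and PTS P80, and with finer clusters it turned to 1.44-fold (0.207 to 16.0) at P60, while 0 cells took this name without doublet removal or with each library clustered alone. The disease-associated microglia list in monocyte/macrophage-like cells measured −0.26 and 1.35, and with Y-linked cells at P60 it measured 0.22 there. The extracellular matrix list in microglia-like cells measured 0.15 and −0.97. In endothelial-like cells MHC class II genes measured 0.79 and −0.90, homeostatic microglia genes 0.51 and −0.76, angiogenic endothelium genes −0.94 and 0.15, extracellular matrix genes −0.54 and 0.15, and mesenchymal-like genes −0.25 and 0.25. Of the endothelial-like values, angiogenic and extracellular matrix genes at P80 turned to −0.12 and −0.09 without doublet removal, and mesenchymal-like genes at P60 to 0.07 with a mean over cells.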

How the results depend on the processing

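The P60 limit to Y-linked cells, doublets at the expected rate in every library and neuroglia without clusters of 1 library were chosen only after the result was seen. Beyond the time point covariate, which the edgeR test already holds, no paired analysis was possible because each surgery and time point has 1 library and the labels give no animal. Of 1136 values of 101 named genes over 6 settings, 15 turned against a direction whose interval left out 0 and 1121 did not, and of 279 alternative values of the main results 167 stayed the same by the rule used. With mitochondrial UMIs of at most 10% and with thinning to 1000 UMIs, the folds of shares and of cycling shares (PTS over sham) stayed within their intervals. All settings fixed in advance were run. Where values moved, the cause was not tested, except that a lower fold limit, no minimum CPM and no filter on low counts let more genes count by construction.

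With a 1.5-fold limit, 45 genes were higher and 109 lower in microglia-like, 28 and 92 in monocyte/macrophage-like cells and 53 and 153 in neuroglia. With no minimum CPM the counts were 20 and 17 in microglia-like cells and 33 and 63 in neuroglia, with 37 lower in monocyte/macrophage-like cells, and r in microglia-like cells was 0.267. With a pseudocount of 5 CPM they were 5 and 2 in monocyte/macrophage-like cells, 5 and 14 in neuroglia, and 2 lower in microglia-like cells. TMM scaling gave 20 and 4 in microglia-like cells, with homeostatic medians of −0.21 and −0.52. A mean over cells gave 18 lower genes in monocyte/macrophage-like cells and 2 lower lists in neuroglia (inflammatory cytokines and the astrocyte-like state), and turned Klrk1 in microglia-like cells at P60 to 0.0652 and Tfap2c in neuroglia at P80 to −5.05e-05.

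DESeq2 called 5 higher and 8 lower genes in endothelial-like, 96 and 84 in microglia-like, 5 and 2 in monocyte/macrophage-like and 41 and 24 in oligodendrocyte-like cells, and 6 and 9 in neuroglia. With no filter on low counts edgeR called 175 and 211 in endothelial-like, 276 and 275 in microglia-like, 27 and 6 in monocyte/macrophage-like and 272 and 133 in oligodendrocyte-like cells, 4 and 1 in neuroglia, 91 and 29 in B/plasma-like, 218 and 87 in T/NK-like, 59 and 43 in dendritic-like and 27 and 30 in choroid plexus-like cells. RLE size factors gave 62 and 15 and doublets at the expected rate 38 and 8 in oligodendrocyte-like cells. Without the covariate there were 0 and 0 in all 9 classes. The difference between P60 and P80 then counts as spread, so this setting cannot show which calls are firm.

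With each library clustered alone edgeR called 15 and 5 in microglia-like, 39 and 4 in B/plasma-like and 0 and 0 in oligodendrocyte-like cells. The concordant genes were then 19 higher in microglia-like cells, 58 lower in monocyte/macrophage-like cells and 42 lower in neuroglia. Shares were 0.815-fold for microglia-like cells at P80, 1.16 and 1.07 for monocyte/macrophage-like cells and 0.637 and 1.34 for neuroglia at P60 and P80. Igkv12-44 (−0.15) and Ror1 (0.20) in choroid plexus-like, Hist1h2ae (−0.93) and Klri1 (−0.46) in dendritic-like and Slpi (−0.45) in endothelial-like cells turned at P60. Finer clusters gave shares at P80 of 1.26 for T/NK-like, 0.660 for microglia-like, 1.38 for monocyte/macrophage-like cells and 1.37 for neuroglia, and turned microglia-like cells at P60 to 0.959. Cells of at least 2000 UMIs gave 0.950 for T/NK-like cells, which turned, and 1.26 for neuroglia at P80.

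Without doublet removal r in microglia-like cells was 0.124, with 7 and 3 concordant genes, 2 higher lists and a homeostatic median of −0.19 at P60, and 13 concordant genes were lower in monocyte/macrophage-like cells. By edgeR 33 genes rose and 16 fell in endothelial-like cells, 4 rose and 0 fell in oligodendrocyte-like cells, and 1 rose in neuroglia. Shares were 0.528 for endothelial-like, 0.682 for microglia-like and 1.13 for monocyte/macrophage-like cells at P80, and 0.847 for neuroglia at P60, while microglia-like cells at P60 turned to 0.853 and neuroglia at P80 to 0.833. Clusters were formed and named anew in this setting, so these values do not show the effect of doublets alone. Cks1b in choroid plexus-like cells (−0.13) and Saa3 in microglia-like cells (−0.40) turned at P80, and Klri1 (−2.67), Slpi (−2.07), Cxcl10 (0.25) and Abca8a (0.38) at P60.

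With P60 limited to Y-linked cells edgeR called 248 and 164 genes in microglia-like, 54 and 37 in monocyte/macrophage-like and 42 and 6 in oligodendrocyte-like cells. Concordant genes were 39 and 48 in microglia-like and 32 and 46 in monocyte/macrophage-like cells, and 27 higher in neuroglia. The homeostatic median at P60 was −0.78, and 1 list was higher and 2 lower in monocyte/macrophage-like cells. Shares at P60 were 43.9 for B/plasma-like, 1.54 for T/NK-like, 0.595 for endothelial-like and 2.29 for monocyte/macrophage-like cells and 0.303 for neuroglia, and microglia-like cells turned to 0.957. Klrk1 in microglia-like cells (0.20) and Fndc3c1 in neuroglia (0.64) turned at P60, and Igf1 in microglia-like cells, whose interval held 0, went from −0.01 to 4.63. The cycling fold of neuroglia at P80 was 1.91 without clusters of 1 library, where 1 list (interferon response) was lower, 2.82 with at least 2 genes and 2.12 without thinning, and at P60 it was 0.884 without thinning.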

Other observations

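The comparison of Y-linked with Xist cells inside sham P60 was chosen only after the sex-linked RNA was seen. Neuroglia made up 29.5% of the Y-linked cells (545 of 1848) and 4.50% of the Xist cells, and neuroblast-like cells, the migrating neuronal precursors, 4.55% and 0.860%. T/NK-like cells were 16.9% and 34.5%, and monocyte/macrophage-like cells 3.79% and 6.70%. Spp1 in microglia-like cells measured 51.2 CPM in Y-linked and 1077 CPM in Xist cells, against 2269 CPM in PTS P60, whereas Chil1 measured 11.7 and 5.13 CPM against 141 CPM. In monocyte/macrophage-like cells Chil1 measured 235 CPM in Y-linked and 8.07 CPM in Xist cells. With Y-linked cells in both P60 libraries, the P60 ratios of microglia-like cells were 4.63 for Igf1, 6.69 for Saa3 and 5.49 for Spp1, against −0.01, 2.03 and 1.71 with all cells, and 3.50 for Chil1.

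Other classes and cell states differed too, without a test. Among microglia-like cells the share of cycling cells at P80 was 17.9% with PTS and 10.2% with sham, and at P60 1.03% and 1.02%. Among T/NK-like cells it was 11.4% with PTS and 7.70% with sham at P60, and 18.5% and 27.7% at P80, but without thinning, which left out 323 PTS and 165 sham cells at P60, the fold there turned to 0.957. Within neuroglia, astrocyte-like cells were 15.7% of all kept cells in PTS P80 and 6.06% in sham P80, while glial progenitor-like cells were 1.49% and 3.31%, but this split is not firm: 2174 of the 3697 astrocyte-like cells of PTS P80 lay in 1 cluster whose scores for the 2 names were close, and a cluster with the same leading genes took the glial progenitor name without doublet removal. The astrocyte-like cluster found nearly only in PTS P80 had egfp at 304 CPM, and its leading genes included Dlk1, Thrsp and Fbp2. A small unnamed cluster led by the mast cell protease genes Mcpt1 and Mcpt2 held 52 of its 56 cells in PTS P80. This does not show that such cells were confined to PTS P80. Without doublet removal a mixed unnamed cluster led by Mcpt1, Mcpt2 and S100a9 held cells of all 4 libraries. These were 104 and 134 cells of sham and PTS at P60, and 143 and 439 at P80.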
